A study of Mus musculus with 126 samples.

How the data were processed

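Small RNA of aorta, brain, duodenum, ileum, jejunum, liver and white adipose tissue (WAT) was sequenced from Ldlr-KO, Pcsk9-KO and C57Bl/6 mice on chow (3% fat) or a Western diet (21% fat, 0.2% cholesterol), begun at week 6 of age and kept to week 22, per the labels. There were 42 groups of 3 libraries, replicates being separate mice per the labels; the organs other than aorta came from 18 mice, and the aortas from 18 mice numbered on their own. The deposited table holds whole-number read counts per mature miRNA and hairpin, from single reads of 50 bases; per the submitters' processing notes DESeq2 and the mm9 build were used, without a stated role or version. The file name says that the table was filtered, by a rule that is not stated; each entry was detected in at least 69 libraries. Of 502 entries, 21 mature names had 2, which are named with their hairpin.

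Columns were assigned to samples by genotype letter, mouse number and organ. For 7 Ldlr-KO libraries title and description disagreed, so only the group was used (unnumbered replicates). For 2 C57Bl/6 libraries title and characteristics disagreed, and the title's group was used. Letters m and f stand in the aorta titles (f in 6), while the protocol names male mice, so sex was not modelled. Totals ran from 1791095 to 34509616 counts.

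For each tissue, entries were filtered with filterByExpr over the 6 groups (minimum count 10), scaled by TMM, and fitted in edgeR 4.0.16 (R 4.3.3) with 1 mean per group, robust dispersions and robust quasi-likelihood, which left 12 residual degrees of freedom. Contrasts were diet averaged over genotypes, Ldlr-KO and Pcsk9-KO against C57Bl/6 averaged over diets, the diet by genotype interaction, and diet within each genotype. F-test p values were adjusted by Benjamini-Hochberg within tissue and contrast, with a threshold of 0.05, and the SE of a log2 fold change was its size divided by the square root of F. Levels are CPM on TMM-scaled library sizes. A miRNA was called enriched in a tissue when its log2 fold change was at least 1 and its adjusted p below 0.05 against each of the 6 other tissues, in a model of all libraries. Named miRNAs followed a rule written before the data were examined: the 3 with the largest rise and fall among those past the threshold with a mean of at least 50 CPM, the members of fixed lists, the 5 enriched miRNAs of highest mean CPM per tissue, the 3 with the smallest interaction p and the 3 most abundant.

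Lists fixed beforehand covered let-7, miR-17-92 paralogs, the miR-183 cluster, the miR-34 family, the Dlk1-Dio3 cluster, lipid metabolism, and markers of hepatocytes, intestinal epithelium, adipocytes, smooth muscle, striated muscle, endothelium, mesenchymal cells, leukocytes, macrophages, erythroid cells, neurons and glia, pancreatic acini and endocrine cells. They were tested with camera and fry in limma 3.58.1 on log2 CPM with a prior count of 2 where at least 3 members were tested, at a preset correlation of 0.01.

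The fit was tested on simulated data. In a simulated diet effect in duodenum on 364 entries, it recovered 45% of changes of 1.5-fold, 89.0% of 2-fold and 98.5% of 4-fold, with 5 false calls among 162, and called 0 when nothing was changed. Recovery at these 3 folds was 40%, 78.1% and 97.0% for Ldlr-KO, 30%, 69.9% and 95.5% for Pcsk9-KO, 10%, 53.4% and 86.2% for diet within C57Bl/6 and 0%, 12.5% and 63.6% for the interaction. The simulated tissue test recovered 200 of 200 at 8-fold on 494 entries. Mouse numbers did not pair libraries across genotypes, so no block was used in those contrasts; organs of 1 mouse did pair (median correlation of residuals 0.124 over 255 pairs of libraries from the same mouse and -0.0713 over 480 others). Alternatives written beforehand were RLE scaling, total-count scaling, DESeq2 1.42.0, no low-count filter, each library left out, a replicate block, an additive model, a fit of the genotype's libraries alone, a stricter enrichment fold, the 2 conflicting libraries left out, and an estimated correlation for lists. After the data were seen, 3 more were added: enrichment without aorta and without a block, without libraries whose median correlation on log2 CPM (pseudocount 1) with their tissue was below 0.95 or whose miR-215-5p share was above 10% outside the small intestine, and 1 entry per mature miRNA. Genome positions were not printed, since the named build differs from that of the annotation at hand.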

Results

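Small RNA was sequenced from 7 organs (aorta, brain, duodenum, ileum, jejunum, liver and white adipose tissue, WAT) of Ldlr-KO, Pcsk9-KO and C57Bl/6 mice fed chow or a Western diet (WD). Ldlr-KO mice lack the LDL receptor, which clears LDL from plasma, and Pcsk9-KO mice lack the secreted protein that sends that receptor to degradation, so the lines differ in opposite ways in LDL clearance. The design held 42 groups of 3 libraries, and the counts covered 502 miRNA entries with 481 mature names, 21 of which had a pair of entries from separate hairpins. Total counts per library ran from 1791095 to 34509616, with a median of 7913960. Median totals per tissue were 8383870 in duodenum, 10014667 in jejunum, 8908228 in ileum, 6128980 in liver, 7886871 in WAT, 4688750 in aorta and 8451860 in brain. The Ldlr and Pcsk9 transcripts are not part of small RNA data, so the targeted genes could not be measured and the genotype labels could not be checked against them. Unless another test is named, log2 fold changes are given ± SE, CPM and percent are mean ± SD, and adjusted p values come from edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment within a tissue and contrast. Diet contrasts compared 9 Western diet with 9 chow libraries, and each knockout contrast compared 6 knockout with 6 C57Bl/6 libraries of the tissue.

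Before the comparisons, 10 libraries stood apart from others of their labelled tissue, by a rule chosen after the data were seen. Of these, 8 were labelled Ldlr-KO, 2 C57Bl/6 and 0 Pcsk9-KO. By label, the 8 were 2 aortas, liver and jejunum of mouse 3, and liver, jejunum, brain and WAT of mouse 5. miR-215-5p, an intestinal epithelial miRNA, took 56.7% (95% Wilson interval 56.6 to 56.7) of the counts in the library labelled Ldlr-KO liver chow replicate 3. It took 63.0% (62.9 to 63.0) in that labelled Ldlr-KO liver WD replicate 5, against at most 1.68% in the remaining 16 liver libraries. The hepatocyte miRNA miR-122-5p had 2 and 1 counts in these, which is 0.00586% (95% Clopper-Pearson interval 7.1e-04 to 0.0212) and 0.00165% (4.2e-05 to 0.00919) of the median of 6982 CPM in the other liver libraries. The miR-215-5p share was 28.1% (95% Wilson interval 28.1 to 28.1) in the library labelled Ldlr-KO WAT WD replicate 5. It was 14.6% (14.6 to 14.6) in that labelled Ldlr-KO brain WD replicate 5. In those labelled C57Bl/6 WAT chow replicates 1 and 2 it was 19.9% (19.9 to 19.97) and 3.69% (3.68 to 3.70). The libraries labelled Ldlr-KO jejunum chow replicate 3 and Western diet replicate 5 had 0.567% (95% Wilson interval 0.563 to 0.572) and 0.471% (0.467 to 0.474) of counts in neuron and glia miRNAs, against at most 0.0479% in the other jejunum libraries. The libraries labelled Ldlr-KO aorta chow replicates 4f and 4m had a median correlation across miRNAs with the other aorta libraries of 0.833 and 0.838. The others had at least 0.981. miRNAs are not independent replicates. Intervals on shares cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Counts are given for all libraries and again without these 10, where the Ldlr-KO aorta chow and C57Bl/6 WAT chow groups keep 1 library that is assumed to vary like the other groups.

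**Figure D1:**
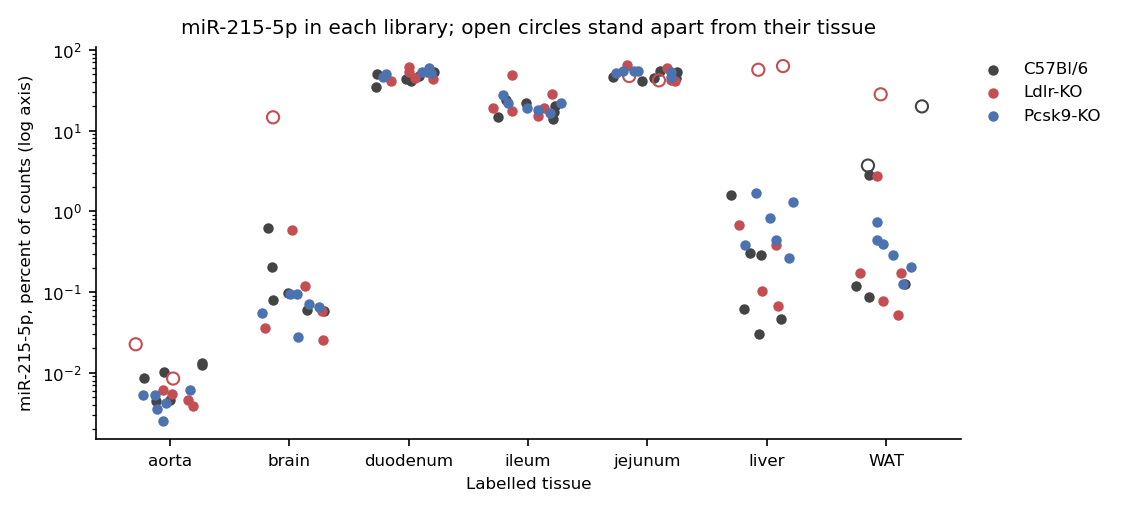
Percent of counts taken by miR-215-5p in each library (log axis) by labelled tissue and genotype; open circles are the 10 libraries that stood apart from their tissue. The 2 open circles in liver sit at 56.7% and 63.0%, above every other liver library.

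The organs differed in which miRNAs dominated. miR-143-3p, known from smooth muscle, took 46.7% ± 14.8 of aorta counts (n = 18), and miR-215-5p took 48.9% ± 6.57 in duodenum, 49.9% ± 6.82 in jejunum and 21.3% ± 7.96 in ileum. miR-22-3p was the most abundant miRNA of liver at 21.2% ± 7.26, and let-7f-5p (let-7f-2) of brain at 8.80% ± 2.06. In WAT miR-10b-5p took 14.4% ± 3.66 and miR-22-3p 14.3% ± 4.20, and without the 3 WAT libraries that stood apart 15.0% ± 2.02 and 15.8% ± 2.01. A miRNA was called enriched in a tissue when it was higher by a log2 fold change of at least 1 than in each of the 6 other tissues at an edgeR adjusted p below 0.05.

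Brain had the most such miRNAs, 130, against 40 in aorta, 15 in liver, 8 in WAT, 7 in ileum and 3 in duodenum, with 18 libraries per tissue. In jejunum 0 passed the edgeR test, and 0 with DESeq2. Without the 10 libraries the numbers were 125 in brain, 28 in aorta, 22 in liver, 11 in WAT, 8 in ileum, 3 in duodenum and 0 in jejunum. Brain held 18 of the 19 neuron and glia entries, among them miR-9-5p (mir-9-3) (16680.2 ± 4220.1 CPM; log2 fold change 6.88 ± 0.56 over jejunum, edgeR adjusted p = 3.4e-22) and miR-128-3p (mir-128-1) (16244 ± 4850.3 CPM; 5.88 ± 0.34 over jejunum, adjusted p = 2.9e-33). It also held 29 of the 30 miRNAs of the imprinted Dlk1-Dio3 locus, among them miR-127-3p (22687 ± 7058 CPM; log2 fold change 3.75 ± 0.27 over aorta, edgeR adjusted p = 6.5e-26). In liver, both hepatocyte miRNAs were enriched, miR-122-5p (5916 ± 4045 CPM; log2 fold change 6.06 ± 0.87 over WAT, edgeR adjusted p = 7.1e-10) and miR-122-3p (599.9 ± 373 CPM; 4.95 ± 0.67 over WAT, adjusted p = 1.1e-10), as was miR-101b-3p (6242 ± 2678 CPM; 3.33 ± 0.24 over brain, adjusted p = 4.2e-26). In aorta, 3 of 4 smooth muscle and 5 of 11 mesenchymal entries were enriched, among them miR-143-3p (458124 ± 189168 CPM; log2 fold change 1.13 ± 0.19 over ileum, edgeR adjusted p = 1.1e-07). The erythroid miR-486-5p was enriched in aorta too (12562 ± 27515 CPM; log2 fold change 3.65 ± 0.60 over WAT, edgeR adjusted p = 6.5e-08), at 2.32 ± 0.52 without the 2 libraries that stood apart there, whereas miR-99b-5p (11935 ± 16636 CPM; 1.77 ± 0.27 over WAT, adjusted p = 1.0e-08) was not enriched without them. Among WAT-enriched miRNAs was miR-10b-5p (82397 ± 21435 CPM; log2 fold change 1.73 ± 0.31 over ileum, edgeR adjusted p = 4.1e-07), and in duodenum both pancreatic acinar miRNAs were enriched, miR-216a-5p (29.6 ± 27.3 CPM; 4.44 ± 0.47 over brain, adjusted p = 1.1e-15) and miR-217-5p (25.1 ± 23.8 CPM; 3.85 ± 0.47 over brain, adjusted p = 4.6e-13). Blocking by mouse, in the 6 organs taken from the same animals, gave 27 in WAT without aorta in the comparison, and leaving out aorta without a block gave 27.

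The diet comparison asked which miRNAs of each organ changed with the Western diet. In duodenum, miR-21a-5p, a miRNA induced in inflammation, fell from 30459 ± 7718 CPM on chow to 17033 ± 3258 on the Western diet (n = 9 each; log2 fold change -0.83 ± 0.15, edgeR adjusted p = 0.00450), lower in 9 of 9 libraries than the chow mean of their genotype. The epithelial miRNAs miR-215-5p (log2 fold change 0.76 ± 0.17, edgeR adjusted p = 0.0137) and miR-141-3p (0.75 ± 0.15, adjusted p = 0.00631) rose, as did miR-30a-3p (0.61 ± 0.12), each in 9 of 9 libraries. miR-142-3p of leukocytes fell (log2 fold change -0.75 ± 0.21, edgeR adjusted p = 0.0346), and so did miR-21a-3p (-0.74 ± 0.19, adjusted p = 0.0292). In all, 21 miRNAs passed the threshold, 13 higher and 8 lower. Of 8 macrophage and inflammation miRNAs, 4 fell and 0 rose (4 and 0 adjusted over the list alone), among them miR-155-5p (-0.95 ± 0.25) and miR-146a-5p (-0.67 ± 0.13). The macrophage and inflammation list had a camera adjusted p of 0.0216, 0.537 with an estimated correlation. Of 7 leukocyte miRNAs, 3 fell and 0 rose (4 and 0 over the list alone; 4 and 0 with total counts; camera adjusted p 0.0730). Of 14 intestinal epithelium entries, 4 rose and 0 fell (8 and 0 over the list alone). Scaling to total counts alone shifted the median of all miRNAs by -0.50, left 1 of them past the threshold and put miR-194-5p (mir-194-2) at -0.05. The intestinal epithelium list had a camera adjusted p of 5.3e-06, 0.355 with an estimated correlation. The duodenum diet count ran from 10 (without C57Bl/6 WD replicate 8) to 29 (without C57Bl/6 chow replicate 2) with 1 library left out. It was 1 higher and 118 lower with total counts. Of the largest duodenum calls, miR-142-3p ended in 13 refits and miR-21a-3p in 1 (highest edgeR adjusted p 0.0890 without C57Bl/6 WD replicate 6, 0.0579 without C57Bl/6 WD replicate 8).

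In jejunum miR-21a-5p fell from 26524 ± 3313 to 12417 ± 1328 CPM (n = 9 each; log2 fold change -1.09 ± 0.08, edgeR adjusted p = 3.7e-07), in 8 of 8 libraries kept. miR-21a-3p (log2 fold change -1.06 ± 0.17, edgeR adjusted p = 0.00307) and miR-96-5p, a member of the SREBP2-driven miR-183 cluster (-0.96 ± 0.20, adjusted p = 0.0110), fell as well. miR-31-5p rose (log2 fold change 0.49 ± 0.08, edgeR adjusted p = 0.00278), and these 3 miRNAs changed in 8 of 8 too. miR-215-5p (log2 fold change 0.66 ± 0.19, edgeR adjusted p = 0.0462) and miR-802-3p (0.50 ± 0.14, adjusted p = 0.0436) were higher. In all, 28 miRNAs passed, 14 higher and 14 lower, and 32 higher and 29 lower without the 2 libraries that carried neuron and glia miRNAs (28 in both). Of 8 macrophage and inflammation miRNAs, 4 fell and 0 rose (4 and 0 over the list alone), with miR-147-3p at -1.83 ± 0.36 and miR-146a-5p at -0.91 ± 0.18. The macrophage and inflammation list had a camera adjusted p of 5.7e-05, 0.355 with an estimated correlation. Of 7 leukocyte miRNAs, 2 fell and 0 rose (2 and 0 over the list alone; 2 and 0 with total counts; camera adjusted p 0.315). Of 14 intestinal epithelium entries, 3 rose and 0 fell (5 and 0 over the list alone), and 1 rose and 1 fell when scaled to total counts, which shifted the median by -0.29. The intestinal epithelium list had a camera adjusted p of 0.00528, 0.904 with an estimated correlation. The jejunum diet count ran from 11 (without C57Bl/6 WD replicate 7) to 53 (without Ldlr-KO chow replicate 3). It was 1 higher and 61 lower with total counts. Of the largest jejunum calls, miR-215-5p ended in 14 refits and miR-802-3p in 14 (highest edgeR adjusted p 0.0997 without C57Bl/6 WD replicate 7, 0.108 without Ldlr-KO WD replicate 6).

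The ileum had the largest diet count of the 3 intestinal segments when all libraries were used, 88 miRNAs, 45 higher and 43 lower. miR-147-3p, induced in macrophages by Toll-like receptor signals, fell from 114 ± 53.9 to 37.7 ± 24.2 CPM (n = 9 each; log2 fold change -1.66 ± 0.28, edgeR adjusted p = 0.00138). miR-21a-3p (log2 fold change -1.13 ± 0.15, edgeR adjusted p = 1.9e-04), miR-96-5p (-1.11 ± 0.19, adjusted p = 0.00108) and miR-21a-5p (-0.99 ± 0.12, adjusted p = 1.7e-04) also fell, the first 2 in 9 of 9 libraries. let-7b-5p rose from 139 ± 69.7 to 292 ± 47.2 CPM (log2 fold change 1.12 ± 0.25, edgeR adjusted p = 0.00605), with let-7c-5p (let-7c-2) at 0.84 ± 0.22 and let-7c-5p (let-7c-1) at 0.73 ± 0.17. Of 12 let-7 entries, 7 rose and 0 fell (7 and 1 over the list alone), and 3 rose and 2 fell when scaled to total counts, which shifted the median by -0.12. Of 8 macrophage and inflammation miRNAs, 5 fell and 0 rose (5 and 0 over the list alone). The macrophage and inflammation list had a camera adjusted p of 0.00108, 0.261 with an estimated correlation. Of 7 leukocyte miRNAs, 3 fell and 1 rose (3 and 1 over the list alone; 3 and 0 with total counts; camera adjusted p 0.419). Of 11 miR-17-92 family entries 3 rose, such as miR-25-3p (0.63 ± 0.12), and 3 fell, such as miR-19a-3p (-0.94 ± 0.26). Of 23 Dlk1-Dio3 miRNAs 5 rose and 0 fell, with 0 past the threshold when scaled to total counts. The ileum diet count ran from 63 (without C57Bl/6 WD replicate 8) to 121 (without Ldlr-KO chow replicate 3). It was 12 higher and 49 lower with total counts. In the ileum refits let-7b-5p, let-7c-5p (let-7c-2), let-7c-5p (let-7c-1), miR-147-3p, miR-21a-3p and miR-96-5p stayed past the threshold.

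**Figure D2:**
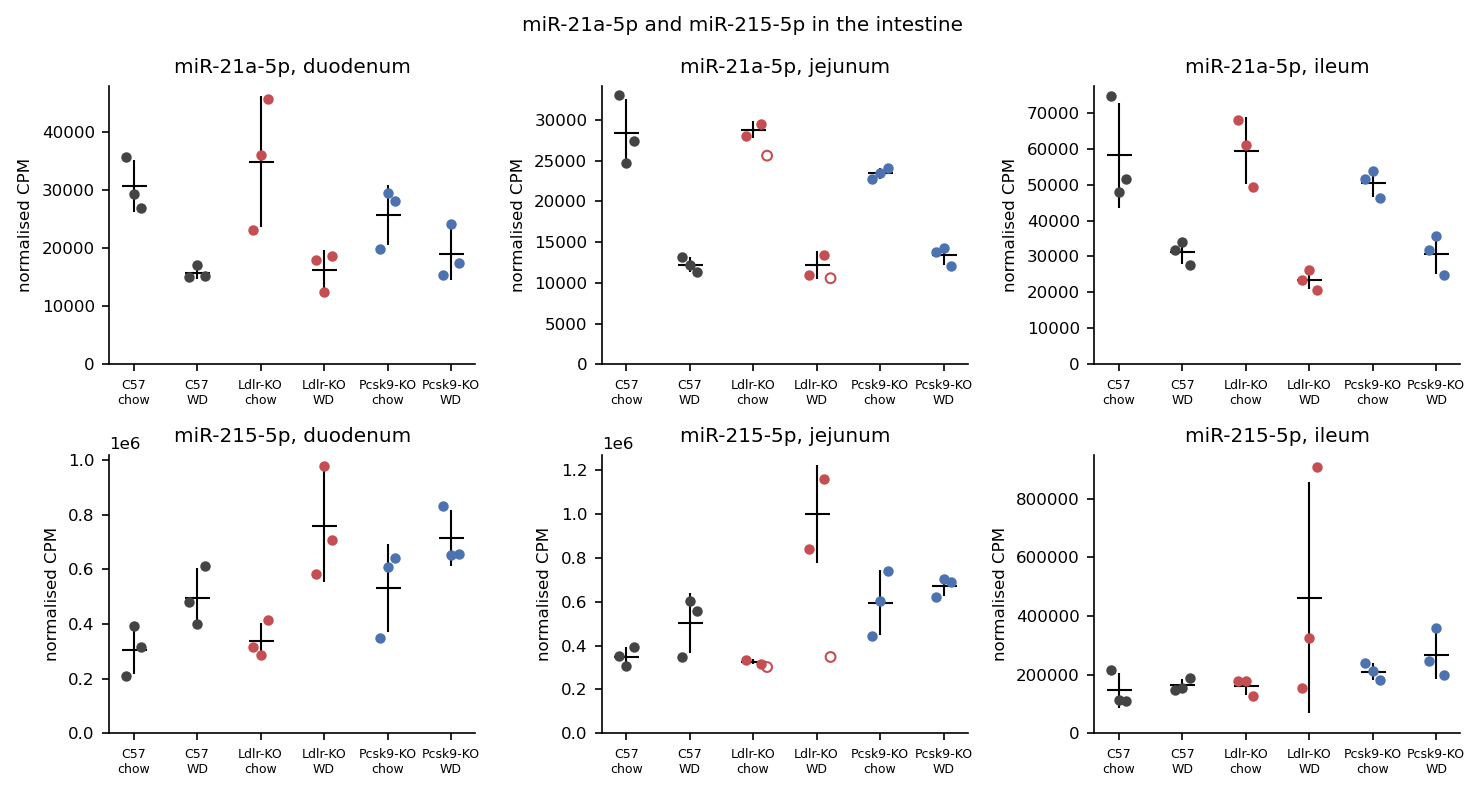
Normalised CPM of miR-21a-5p and miR-215-5p in each library of duodenum, jejunum and ileum by genotype and diet; filled points are libraries, bars are mean ± SD of these, and open circles are libraries that stood apart. In jejunum the mean of miR-21a-5p over genotypes was 26524 CPM on chow and 12417 on the Western diet.

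Whether the diet effect differed between genotypes was tested as an interaction. In duodenum 0 (edgeR; 15 at unadjusted p below 0.05; 0 with DESeq2) miRNAs passed, and in jejunum 0 (edgeR; 18 at unadjusted p below 0.05; 2 with DESeq2). In ileum 3 passed, of which miR-92a-3p (mir-92a-2) was above 50 CPM (edgeR adjusted p = 0.0263). This call ended in 13 of 18 refits without 1 library (highest edgeR adjusted p 0.173, without C57Bl/6 WD replicate 7). Its diet log2 fold change was -0.33 ± 0.18 in C57Bl/6, 0.86 ± 0.18 in Ldlr-KO and 0.86 ± 0.18 in Pcsk9-KO (n = 3 per diet). In ileum 9 of 100 random splits called as many, the highest other 21, so chance could not be excluded. In jejunum, 2 passed without the libraries that stood apart. Within genotypes, with 3 against 3 libraries, the duodenum diet test called 1 in C57Bl/6, 0 in Ldlr-KO (34 at unadjusted p below 0.05; 12 with DESeq2) and 0 in Pcsk9-KO (27 at unadjusted p below 0.05; 0 with DESeq2). The jejunum test called 1 in C57Bl/6, 3 in Ldlr-KO and 1 in Pcsk9-KO, and the ileum test 60 in C57Bl/6, 9 in Ldlr-KO and 0 in Pcsk9-KO (38 at unadjusted p below 0.05; 6 with DESeq2). In simulated duodenum data the interaction test recovered 12.5% of 2-fold changes, and the diet test within C57Bl/6 53.4%. For jejunum the counts within genotypes were 12, 20 and 1 in the same order without the libraries that stood apart.

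The knockout comparisons asked which miRNAs differed in each organ from C57Bl/6 when the LDL receptor or Pcsk9 was absent. In duodenum of Ldlr-KO mice the let-7 family was lower: 10 of 12 entries fell and 0 rose (11 and 0 over the list alone). The let-7 list had a camera adjusted p of 7.9e-11, 0.409 with an estimated correlation. let-7d-5p fell from 1029 ± 99.2 to 438 ± 138.3 CPM (n = 6 each; log2 fold change -1.24 ± 0.19, edgeR adjusted p = 0.00131), lower in 6 of 6 libraries than the C57Bl/6 mean on the same diet. let-7a-5p (let-7a-2) (log2 fold change -1.29 ± 0.22, edgeR adjusted p = 0.00261) and let-7b-5p (-1.41 ± 0.35, adjusted p = 0.0266) fell too. miR-136-3p (log2 fold change 1.02 ± 0.20, edgeR adjusted p = 0.00554), miR-21a-3p (0.81 ± 0.24, adjusted p = 0.0445) and miR-145a-3p (0.78 ± 0.23, adjusted p = 0.0439) rose. In all 27 passed, 10 higher and 17 lower. Scaling to total counts shifted the median by -0.23 and put 10 let-7 entries lower. The duodenum Ldlr-KO count ran from 7 (without Ldlr-KO WD replicate 6) to 55 (without Ldlr-KO chow unnumbered replicate). Of the largest duodenum calls, miR-21a-3p ended in 9 refits, miR-145a-3p in 8 and let-7b-5p in 6 (highest edgeR adjusted p 0.0993 and 0.105 without Ldlr-KO chow replicate 3, 0.0853 without C57Bl/6 WD replicate 8).

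In duodenum of Pcsk9-KO mice 16 miRNAs passed, 10 higher and 6 lower. let-7d-5p (log2 fold change -0.84 ± 0.19, edgeR adjusted p = 0.0192), miR-30b-5p (-0.68 ± 0.16, adjusted p = 0.0192) and miR-181a-5p (mir-181a-2) (-0.66 ± 0.15, adjusted p = 0.0192) fell in 6 of 6 libraries. Both miR-136-3p (log2 fold change 0.90 ± 0.20, edgeR adjusted p = 0.0192) and miR-99b-5p (0.65 ± 0.17, adjusted p = 0.0394) rose, also in 6 of 6. The duodenum Pcsk9-KO count ran from 1 (without C57Bl/6 WD replicate 8) to 26 (without C57Bl/6 chow replicate 2). It was 0 higher and 51 lower with total counts. Of the largest duodenum calls, miR-136-3p ended in 6 refits, miR-99b-5p in 12, let-7d-5p in 2, miR-30b-5p in 1 and miR-181a-5p (mir-181a-2) in 3 (highest edgeR adjusted p 0.0786, 0.115, 0.0725, 0.0725 and 0.0786 without C57Bl/6 WD replicate 8). In jejunum, let-7d-5p was the only miRNA past the threshold in Ldlr-KO (log2 fold change -0.80 ± 0.12, edgeR adjusted p = 0.00472), as without the libraries that stood apart, and lower in 4 of 4 libraries kept. The jejunum Ldlr-KO count ran from 1 (without C57Bl/6 chow replicate 1) to 74 (without Ldlr-KO chow unnumbered replicate). It was 54 with DESeq2. In the jejunum refits let-7d-5p stayed past the threshold. With total-count scaling its edgeR adjusted p was 0.107 (log2 fold change -0.89 ± 0.23).

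In jejunum of Pcsk9-KO mice miR-30b-5p fell from 709 ± 109 to 403 ± 44.6 CPM (n = 6 each; log2 fold change -0.80 ± 0.09, edgeR adjusted p = 1.6e-04), in 6 of 6 libraries. The 2 entries of miR-30c-5p, which targets a lipoprotein assembly gene, had equal counts in 81.0% of libraries, and fell: mir-30c-1 (log2 fold change -0.80 ± 0.20, edgeR adjusted p = 0.0350) and mir-30c-2 (-0.64 ± 0.16, adjusted p = 0.0350). miR-145a-3p (log2 fold change 0.76 ± 0.19, edgeR adjusted p = 0.0350), miR-30a-3p (0.57 ± 0.12, adjusted p = 0.0163) and miR-25-3p (0.54 ± 0.11, adjusted p = 0.0124) rose. In all 16 passed, 4 higher and 12 lower, and 21 higher and 28 lower without the libraries that stood apart (16 in both). The jejunum Pcsk9-KO count ran from 5 (without C57Bl/6 WD replicate 6) to 19 (without C57Bl/6 chow replicate 2). It was 30 with DESeq2 and 0 higher and 57 lower with total counts. Of the largest jejunum calls, miR-145a-3p ended in 11 refits, miR-30c-5p (mir-30c-2) in 10, miR-25-3p in 5 and miR-30c-5p (mir-30c-1) in 8 (highest edgeR adjusted p 0.119 and 0.109 without C57Bl/6 chow replicate 3, 0.0882 without Pcsk9-KO chow replicate 2, 0.0975 without Pcsk9-KO WD replicate 5).

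In ileum miR-100-5p, of the miR-99/100 family, rose from 384 ± 116 CPM in C57Bl/6 to 811 ± 176 in Ldlr-KO (log2 fold change 1.10 ± 0.18, edgeR adjusted p = 0.00336) and 794 ± 158 in Pcsk9-KO (1.07 ± 0.18, adjusted p = 0.00413; n = 6 each), both against the same C57Bl/6 libraries. The related miR-99a-5p was higher in Ldlr-KO (log2 fold change 0.99 ± 0.26, edgeR adjusted p = 0.0374) and in Pcsk9-KO (1.01 ± 0.26, adjusted p = 0.0233). In Ldlr-KO, 19 miRNAs passed, 11 higher and 8 lower. The leukocyte miRNA miR-142-5p was higher (log2 fold change 0.88 ± 0.21, edgeR adjusted p = 0.0206). Lower were miR-92a-3p (mir-92a-1) (log2 fold change -0.58 ± 0.11, edgeR adjusted p = 0.00746), the muscle miRNA miR-133a-3p (-0.70 ± 0.15, adjusted p = 0.0185) and the smooth muscle miRNA miR-145a-5p (-0.87 ± 0.20, adjusted p = 0.0194). The ileum Ldlr-KO count ran from 6 (without C57Bl/6 chow replicate 3) to 28 (without C57Bl/6 chow replicate 1). It was 45 with DESeq2 and 0 higher and 12 lower with total counts. Of the largest ileum calls, miR-99a-5p ended in 10 refits, miR-145a-5p in 2 and miR-142-5p in 6 (highest edgeR adjusted p 0.138 and 0.0518 without C57Bl/6 WD replicate 8, 0.0795 without C57Bl/6 chow replicate 3).

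In ileum of Pcsk9-KO mice 34 miRNAs passed, 17 higher and 17 lower. miR-147-3p (log2 fold change -1.38 ± 0.34, edgeR adjusted p = 0.0226), miR-138-5p (mir-138-1) (-0.97 ± 0.19, adjusted p = 0.00578) and the leukocyte miRNA miR-142-3p (-0.91 ± 0.22, adjusted p = 0.0181) fell in 6 of 6 libraries, and the mesenchymal miR-199b-3p rose (1.29 ± 0.37, adjusted p = 0.0410). Scaling to total counts shifted the median by -0.45 and put miR-126a-5p, an endothelial miRNA that was higher (0.42 ± 0.12), at -0.04. The ileum Pcsk9-KO count ran from 15 (without Pcsk9-KO chow replicate 2) to 43 (without Ldlr-KO WD replicate 5). It was 1 higher and 87 lower with total counts. Of the largest ileum calls, miR-199b-3p ended in 12 refits, miR-99a-5p in 6, miR-147-3p in 8 and miR-142-3p in 1 (highest edgeR adjusted p 0.112 without C57Bl/6 WD replicate 8, 0.0975 without C57Bl/6 WD replicate 7, 0.0614 without C57Bl/6 chow replicate 1, 0.0558 without Pcsk9-KO chow replicate 2).

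In liver the Western diet raised miR-582-3p, which went from 15.9 ± 33.8 to 99.3 ± 48.7 CPM (n = 9 each; log2 fold change 3.44 ± 0.56, edgeR adjusted p = 0.00195, 10.8-fold), higher in 8 of 8 libraries kept. Without the 2 gut-like libraries it rose 20.1-fold (4.33 ± 0.33). miRNAs of the imprinted Dlk1-Dio3 locus fell: 9 of 14 measured members fell and 0 rose (12 and 0 over the list alone), and 16 of 16 without the 2 libraries. The Dlk1-Dio3 list had a camera adjusted p of 3.4e-08, 0.740 with an estimated correlation. The falling members included miR-127-3p (log2 fold change -1.54 ± 0.39, edgeR adjusted p = 0.0204), miR-411-5p (-1.47 ± 0.37, adjusted p = 0.0204), miR-434-3p (-1.82 ± 0.38, adjusted p = 0.00659) and miR-409-3p (-2.31 ± 0.38, adjusted p = 0.00195). miR-146b-5p, which is induced by NF-kappaB and restrains inflammatory signalling, rose (log2 fold change 0.98 ± 0.24, edgeR adjusted p = 0.0167). So did miR-335-5p (log2 fold change 0.80 ± 0.24, edgeR adjusted p = 0.0408) and miR-34a-5p, a p53 target (2.47 ± 0.28, adjusted p = 1.5e-04), whereas let-7d-3p fell (-2.10 ± 0.53, adjusted p = 0.0204). Of 29 lipid metabolism entries, 1 rose and 3 fell (1 and 3 over the list alone), with miR-33-5p, encoded in Srebf2, at log2 fold change -0.93 ± 0.20, edgeR adjusted p = 0.00930. Without the 2 libraries 5 rose and 11 fell. In all 53 passed, 18 higher and 35 lower, and 56 higher and 86 lower without the 2 libraries (53 in both). The liver diet count ran from 30 (without C57Bl/6 WD replicate 6) to 100 (without Ldlr-KO WD replicate 5). It was 84 with DESeq2. Of the largest liver calls, miR-146b-5p ended in 2 refits, miR-127-3p in 1, miR-411-5p in 1, miR-335-5p in 16 and let-7d-3p in 2 (highest edgeR adjusted p 0.0652, 0.0593 and 0.0502 without Pcsk9-KO WD replicate 7, 0.136 without Ldlr-KO WD replicate 6, 0.0505 without Ldlr-KO chow replicate 2).

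In liver of the mice labelled Ldlr-KO, 100 miRNAs passed against C57Bl/6, 66 higher and 34 lower, and 25 higher and 40 lower without the 2 gut-like libraries (46 in both), of which both carry this label. The intestinal miRNAs miR-215-5p (log2 fold change 8.33 ± 2.02, edgeR adjusted p = 0.0147), miR-194-1-3p (6.96 ± 1.95, adjusted p = 0.0211) and miR-215-3p (6.38 ± 1.81, adjusted p = 0.0215) were highest. Without the 2 libraries they stood at 0.35 ± 0.59, -1.15 ± 0.74 and -0.72 ± 0.78, with edgeR adjusted p values of 0.706, 0.310 and 0.567. Likewise 10 of 14 intestinal epithelium entries were higher with all libraries (10 over the list alone), and without the 2 libraries 0 were higher and 1 lower. Among calls that stood in both fits was the erythroid miR-486-5p (log2 fold change -3.23 ± 0.72, edgeR adjusted p = 0.0147; -3.17 ± 0.94 without the 2). The same held for let-7d-3p (log2 fold change -2.76 ± 0.67, edgeR adjusted p = 0.0147; -2.43 ± 0.75) and miR-193a-3p (-1.95 ± 0.53, adjusted p = 0.0197; -1.48 ± 0.20), and all 3 were lower in 4 of 4 libraries kept. The liver level of miR-146b-5p was higher (log2 fold change 2.38 ± 0.30, edgeR adjusted p = 5.3e-04; 1.99 ± 0.23). Of 4 erythroid miRNAs 3 fell and 0 rose (4 and 0 over the list alone) and 3 without the 2 libraries. When scaled to total counts, which shifted the median by -0.50, 1 fell. The erythroid list had a camera adjusted p of 0.0138, 0.904 with an estimated correlation. The liver Ldlr-KO count ran from 22 (without C57Bl/6 WD replicate 7) to 123 (without Ldlr-KO chow replicate 2). It was 17 higher and 38 lower with total counts. Of the largest liver calls, miR-215-5p ended in 4 refits, let-7d-3p in 1, miR-193a-3p in 4, miR-194-1-3p in 7 and miR-215-3p in 7 (highest edgeR adjusted p 0.0589, 0.0517 and 0.0641 without C57Bl/6 WD replicate 7, 0.291 and 0.256 without Ldlr-KO WD replicate 5).

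In liver of Pcsk9-KO mice let-7 miRNAs were higher: 6 of 12 entries rose and 1, let-7b-5p, fell (7 and 1 over the list alone), while 0 passed in edgeR when scaled to total counts, which shifted the median by -0.35. The let-7 list had a camera adjusted p of 0.00453, 0.740 with an estimated correlation. let-7f-5p (let-7f-1) rose from 538 ± 199.96 to 1144 ± 105.8 CPM (n = 6 each; log2 fold change 1.16 ± 0.17, edgeR adjusted p = 0.00171) and let-7e-5p likewise (1.08 ± 0.19, adjusted p = 0.00366), in 6 of 6 libraries. miR-146b-5p rose (log2 fold change 1.19 ± 0.29, edgeR adjusted p = 0.0224). The lymphocyte miRNA miR-150-5p (log2 fold change -1.47 ± 0.27, edgeR adjusted p = 0.00635), miR-125a-5p (-1.05 ± 0.20, adjusted p = 0.00678) and miR-30b-5p (-0.76 ± 0.16, adjusted p = 0.00957) fell in 6 of 6. In all 35 passed, 16 higher and 19 lower, and 47 higher and 55 lower without the 2 gut-like libraries (35 in both). There 7 of 14 intestinal epithelium entries rose. Kept C57Bl/6 libraries held 0.0303% miR-215-5p (chow replicate 3) to 1.60% (WD replicate 6), so mixed reads stay open. The liver Pcsk9-KO count ran from 9 (without C57Bl/6 WD replicate 7) to 52 (without Ldlr-KO chow replicate 3). Of the largest liver calls, miR-146b-5p ended in 4 refits and miR-30b-5p in 1 (highest edgeR adjusted p 0.0755 without Pcsk9-KO WD replicate 7, 0.0543 without C57Bl/6 WD replicate 7). In the interaction test 0 (edgeR; 26 at unadjusted p below 0.05; 2 with DESeq2) miRNAs passed, and 4 without the 2 libraries. Within genotypes the diet test called 33 in C57Bl/6, 0 in Ldlr-KO (33 at unadjusted p below 0.05; 2 with DESeq2) and 0 in Pcsk9-KO (31 at unadjusted p below 0.05; 10 with DESeq2), and 120, 62 and 21 without them.

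In WAT the Western diet raised both arms of miR-335, whose hairpin lies in the imprinted gene Mest: miR-335-3p (log2 fold change 1.89 ± 0.48, edgeR adjusted p = 0.0251) and miR-335-5p (1.46 ± 0.38, adjusted p = 0.0269). miR-298-5p rose from 23.2 ± 9.56 to 118 ± 51.7 CPM (n = 9 each; log2 fold change 2.33 ± 0.33, edgeR adjusted p = 9.2e-04), in 8 of 8 libraries kept. miR-193a-3p (log2 fold change -1.38 ± 0.29, edgeR adjusted p = 0.00752) and miR-103-3p (mir-103-1), linked to insulin sensitivity (-1.35 ± 0.28, adjusted p = 0.00752), fell. miR-34c-5p was lower with all libraries (log2 fold change -2.06 ± 0.55, edgeR adjusted p = 0.0301) and stood at -0.82 ± 0.35, adjusted p = 0.116, without the 3 WAT libraries that stood apart. Of 7 adipocyte and thermogenic miRNAs 3 fell and 0 rose (4 and 0 over the list alone), namely miR-193a-3p, miR-378a-3p (-1.02 ± 0.16) and miR-378a-5p (-1.07 ± 0.19), and 1 fell when scaled to total counts. The adipocyte and thermogenic list had a camera adjusted p of 0.0124, 0.355 with an estimated correlation. Of 7 leukocyte miRNAs 2 rose and 0 fell (3 and 0 over the list alone), miR-142-5p (0.85 ± 0.17) and miR-342-3p (0.96 ± 0.18), and 4 without the 3 libraries. The leukocyte list had a camera adjusted p of 0.0216, 0.537 with an estimated correlation. In all 40 passed, 17 higher and 23 lower, and 35 higher and 60 lower without the 3 libraries (36 in both), where 9 of 14 intestinal epithelium entries were lower. Kept chow libraries also held intestinal miRNAs. miR-215-5p was 2.83% in C57Bl/6 chow replicate 3, the only library left in its group, and 2.75% in Ldlr-KO chow replicate 3. Kept Western diet WAT libraries held at most 0.729%. Of 28 Dlk1-Dio3 miRNAs 2 rose and 0 fell in WAT (2 and 0 over the list alone). These were 2 and 0 without the 3 libraries, and 0 and 0 when scaled to total counts. The Dlk1-Dio3 list had a camera adjusted p of 5.7e-05, 0.594 with an estimated correlation. The WAT diet count ran from 23 (without Pcsk9-KO WD replicate 6) to 48 higher and 78 lower (without Ldlr-KO WD replicate 5). It was 13 higher and 6 lower with total counts. Of the largest WAT calls, miR-335-3p ended in 4 refits, miR-335-5p in 7 and miR-34c-5p in 12 (highest edgeR adjusted p 0.0531 without Pcsk9-KO chow replicate 3, 0.0580 without C57Bl/6 WD replicate 7, 0.0808 without Pcsk9-KO WD replicate 5).

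In WAT of Ldlr-KO mice let-7c-5p (let-7c-2) (log2 fold change -1.07 ± 0.20, edgeR adjusted p = 0.0102), let-7b-5p (-0.85 ± 0.17, adjusted p = 0.0160) and miR-744-5p (-0.93 ± 0.17, adjusted p = 0.0102) fell in 5 of 5 libraries kept. In all 8 passed, 3 higher and 5 lower, and 2 higher and 6 lower without the 3 libraries (5 in both). The WAT Ldlr-KO count ran from 4 (without C57Bl/6 chow replicate 2) to 31 (without Ldlr-KO WD replicate 5). It was 21 with DESeq2 and 1 higher and 4 lower with total counts. Of the largest WAT calls, let-7b-5p ended in 2 refits (highest edgeR adjusted p 0.0624 without C57Bl/6 chow replicate 2). In Pcsk9-KO WAT the hepatocyte miRNA miR-122-5p was higher, at 332 ± 306 CPM against 71.0 ± 116 (n = 6 each; log2 fold change 4.89 ± 1.07, edgeR adjusted p = 0.0220; 5.39 ± 1.45, adjusted p = 0.0417, without the 3 libraries), but in 4 of 6 libraries only. This change averages over diets and leans on C57Bl/6 chow, where miR-122-5p stood at 0.905 ± 0.884 CPM (n = 3), against 141.1 ± 137.6 in C57Bl/6 on the Western diet. miR-674-3p (log2 fold change 1.13 ± 0.29, edgeR adjusted p = 0.0356) and let-7f-5p (let-7f-1) (0.79 ± 0.16, adjusted p = 0.0220) rose, and miR-145a-5p of smooth muscle fell (-1.92 ± 0.45, adjusted p = 0.0220; -1.17 ± 0.24 without the 3 libraries). miR-34c-5p (log2 fold change -2.95 ± 0.70, edgeR adjusted p = 0.0239) and miR-103-3p (mir-103-1) (-1.30 ± 0.34, adjusted p = 0.0378) were lower with all libraries and not past the threshold without the 3 (-1.01 ± 0.43, adjusted p = 0.182, and -1.10 ± 0.41, adjusted p = 0.135). In all 24 passed, 12 higher and 12 lower, and 25 higher and 20 lower without the 3 (19 in both). The WAT Pcsk9-KO count ran from 0 (without C57Bl/6 WD replicate 7) to 78 (without Ldlr-KO WD replicate 5). It was 42 with DESeq2. Of the largest WAT calls, miR-122-5p ended in 4 refits, miR-674-3p in 9, let-7f-5p (let-7f-1) in 5, miR-34c-5p in 9, miR-145a-5p in 6 and miR-103-3p (mir-103-1) in 12 (highest edgeR adjusted p 0.0537 without C57Bl/6 chow replicate 2, 0.120 without C57Bl/6 WD replicate 7, 0.0625 without Pcsk9-KO WD replicate 6, 0.0778 without Pcsk9-KO WD replicate 5, 0.0691 and 0.131 without Pcsk9-KO chow replicate 2). In the WAT interaction test 0 (edgeR; 77 at unadjusted p below 0.05; 29 with DESeq2) miRNAs passed, and 9 without the 3 libraries. Within WAT genotypes the diet test called 21 in C57Bl/6, 9 in Ldlr-KO and 1 in Pcsk9-KO, and 37, 57 and 23 without them.

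In aorta, the vessel where atherosclerotic lesions form, miR-146b-5p (log2 fold change 1.36 ± 0.30, edgeR adjusted p = 0.0422; 7 of 9 libraries) and the p53 target miR-34c-5p (0.97 ± 0.24, adjusted p = 0.0452; 8 of 9) rose with the Western diet. Without the 2 aorta libraries that stood apart these were 1.02 ± 0.23 and 0.67 ± 0.14, both past the threshold (edgeR adjusted p = 0.0259 and 0.0182). let-7d-3p (log2 fold change -1.94 ± 0.43, edgeR adjusted p = 0.0422), miR-328-3p (-1.79 ± 0.41, adjusted p = 0.0422) and miR-92b-3p (-1.79 ± 0.43, adjusted p = 0.0452) were lower with all libraries. Without the 2 these stood at -0.35 ± 0.12, -0.35 ± 0.12 and -0.25 ± 0.16, none past the threshold in edgeR (adjusted p = 0.213, 0.211 and 0.596). Of 5 miR-34 family miRNAs 2 rose and 0 fell (4 and 0 over the list alone), and 3 without the 2. The miR-34 family list had a camera adjusted p of 0.0137, 0.355 with an estimated correlation. Of 7 macrophage and inflammation miRNAs 1 rose and 0 fell (3 and 0 over the list alone), and 3 without the 2, among them miR-21a-5p (log2 fold change 0.47 ± 0.11, edgeR adjusted p = 0.0291). The macrophage and inflammation list had a camera adjusted p of 0.00479, 0.904 with an estimated correlation. In all 9 passed, 3 higher and 6 lower, and 10 higher and 2 lower without the 2 (3 in both). The aorta diet count ran from 0 (without C57Bl/6 WD replicate 11m) to 272 (without Ldlr-KO chow replicate 3m). It was 71 with DESeq2. Of the largest aorta calls, miR-146b-5p ended in 16 refits, let-7d-3p in 16, miR-328-3p in 16, miR-92b-3p in 17 and miR-34c-5p in 16 (highest edgeR adjusted p 0.119, 0.119, 0.119 and 0.119 without Ldlr-KO WD unnumbered replicate, 0.126 without C57Bl/6 WD replicate 11m).

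The interaction test in aorta called 66 miRNAs with all libraries and 11 without the 2 that stood apart, of which 4 were called in both. The count with all libraries ran from 0 (without Ldlr-KO WD unnumbered replicate) to 293 (without Ldlr-KO chow replicate 3m) with 1 library left out. In aorta 7 of 100 random splits called as many, the highest other 73, so chance could not be excluded for it. Without the libraries that stood apart 2 of 100 random splits called as many, the highest other 12. Without them, miR-21a-5p stood at 15343 ± 3077 CPM in Ldlr-KO mice on the Western diet (n = 3), against 4315 ± 556 in C57Bl/6 and 5175 ± 834 in Pcsk9-KO on that diet. The 1 Ldlr-KO chow library left was at 4992 CPM (interaction edgeR adjusted p = 0.00748; 0.132 with all libraries). miR-34c-5p rose with diet by 1.73 ± 0.32 in Ldlr-KO and stood at -0.03 ± 0.20 in C57Bl/6 and 0.31 ± 0.21 in Pcsk9-KO (interaction edgeR adjusted p = 0.0391; 0.0187 with all libraries). For miR-146b-5p these were 2.11 ± 0.52, 0.67 ± 0.32 and 0.29 ± 0.32 (interaction edgeR adjusted p = 0.333; 0.0320 with all libraries). By diet within genotypes the test called 0 in C57Bl/6 (8 at unadjusted p below 0.05; 1 with DESeq2), 135 in Ldlr-KO and 0 in Pcsk9-KO (10 at unadjusted p below 0.05; 0 with DESeq2), and 2, 11 and 0 without the 2 libraries.

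In aorta of Ldlr-KO mice miR-423-5p was higher (log2 fold change 2.94 ± 0.46, edgeR adjusted p = 0.00217; 1.30 ± 0.20 without the 2 libraries that stood apart) and miR-30b-5p lower (-1.36 ± 0.29, adjusted p = 0.00755; -0.84 ± 0.15), in 4 of 4 libraries kept. miR-214-3p (log2 fold change 2.25 ± 0.48, edgeR adjusted p = 0.00755), miR-574-3p (2.21 ± 0.47, adjusted p = 0.00755), miR-193a-3p (-1.54 ± 0.49, adjusted p = 0.0330) and miR-26a-5p (mir-26a-1) (-1.23 ± 0.38, adjusted p = 0.0278) passed with all libraries. Without the 2 they did not (edgeR adjusted p = 0.264, 0.196, 0.149 and 0.124). let-7e-5p rose in both fits (log2 fold change 1.03 ± 0.16, edgeR adjusted p = 0.00217; 1.00 ± 0.15 without the 2), and 3 of 12 let-7 entries rose with all libraries (3 over the list alone) and 5 without the 2. Of 5 miR-34 family miRNAs 3 were higher (3 over the list alone) and 3 without the 2. In all 95 passed, 71 higher and 24 lower, and 24 higher and 10 lower without the 2 (19 in both). The aorta Ldlr-KO count ran from 35 (without C57Bl/6 WD replicate 11m) to 285 (without Ldlr-KO chow replicate 3m). Of the largest aorta calls, miR-193a-3p ended in 17 refits and miR-26a-5p (mir-26a-1) in 8 (highest edgeR adjusted p 0.108 without C57Bl/6 chow replicate 4f, 0.0781 without C57Bl/6 chow replicate 3m).

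In aorta of Pcsk9-KO mice miR-31-5p fell from 296 ± 46.5 to 79.0 ± 10.3 CPM (n = 6 each; log2 fold change -1.91 ± 0.17, edgeR adjusted p = 2.6e-06), in 6 of 6 libraries. miR-100-5p (log2 fold change -1.18 ± 0.24, edgeR adjusted p = 0.00982) and miR-224-5p (-1.17 ± 0.25, adjusted p = 0.0188) also fell in 6 of 6. In the same contrast let-7e-5p (log2 fold change 0.93 ± 0.16, edgeR adjusted p = 0.00240) and miR-30a-3p (0.52 ± 0.13, adjusted p = 0.0475) rose, in 6 of 6. In all 11 passed, 8 higher and 3 lower, and 38 higher and 45 lower without the 2 Ldlr-KO libraries (11 in both), which enter this contrast through the shared estimate of spread. The aorta Pcsk9-KO count ran from 5 (without C57Bl/6 WD replicate 11m) to 88 (without Ldlr-KO chow replicate 3m). It was 27 with DESeq2 and 3 higher and 30 lower with total counts. Of the largest aorta calls, miR-30a-3p ended in 15 refits, miR-100-5p in 8 and miR-224-5p in 14 (highest edgeR adjusted p 0.182 without C57Bl/6 chow replicate 3m, 0.0755 without C57Bl/6 WD replicate 11m, 0.118 without Pcsk9-KO chow replicate 3m).

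**Figure D3:**
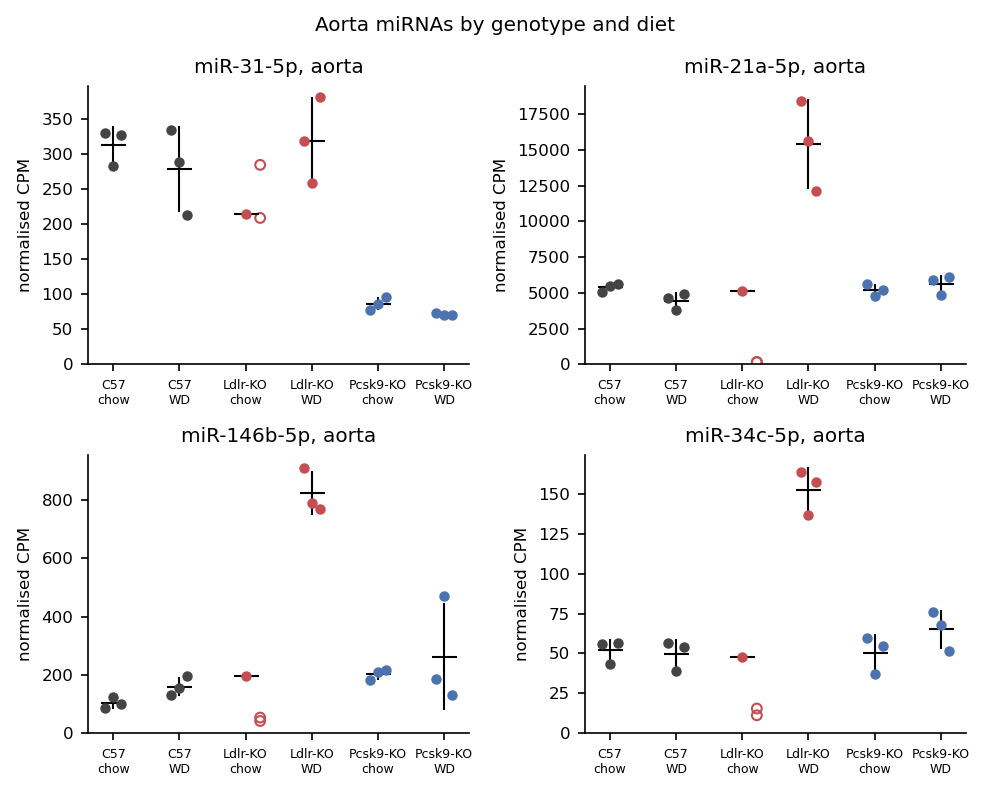
Normalised CPM of miR-31-5p, miR-21a-5p, miR-146b-5p and miR-34c-5p in each aorta library by genotype and diet; filled points are libraries, bars are mean ± SD of these, and open circles are the 2 libraries that stood apart. miR-31-5p averaged 296 CPM in C57Bl/6 and 79.0 in Pcsk9-KO.

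In brain on the Western diet miR-338-3p, an oligodendrocyte miRNA, fell from 6447 ± 1673 to 4115 ± 964 CPM (n = 9 each; log2 fold change -0.67 ± 0.16, edgeR adjusted p = 0.0418). miR-29a-5p (log2 fold change -1.06 ± 0.24, edgeR adjusted p = 0.0418) and miR-376a-5p (-0.72 ± 0.16, adjusted p = 0.0418) fell too, and all 3 did so in 8 of 8 libraries kept. miR-674-3p (log2 fold change 0.60 ± 0.13, edgeR adjusted p = 0.0418), miR-191-5p (0.54 ± 0.14, adjusted p = 0.0484) and miR-1843b-3p (0.72 ± 0.19, adjusted p = 0.0484) rose. The last 2 did not pass without the library that carried miR-215-5p (edgeR adjusted p = 0.0599 and 0.0542). In all 19 passed, 9 higher and 10 lower, and 5 higher and 13 lower without that library (10 in both). The brain diet count ran from 0 (without C57Bl/6 chow replicate 1) to 97 (without Ldlr-KO chow unnumbered replicate). It was 49 with DESeq2 and 2 higher and 48 lower with total counts. Of the largest brain calls, miR-1843b-3p ended in 15 refits, miR-674-3p in 14, miR-191-5p in 15, miR-29a-5p in 14, miR-376a-5p in 14 and miR-338-3p in 14 (highest edgeR adjusted p 0.125, 0.0969, 0.116, 0.0840, 0.0840 and 0.0840 without Pcsk9-KO chow replicate 3). Also, 9 passed with RLE scaling and 0 with an additive model of genotype and diet.

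In brain of Ldlr-KO mice miR-100-5p rose from 3761 ± 427 to 7866 ± 1656 CPM (n = 6 each; log2 fold change 1.05 ± 0.15, edgeR adjusted p = 0.00203). So did miR-409-5p of the Dlk1-Dio3 locus (log2 fold change 1.34 ± 0.25, edgeR adjusted p = 0.00906) and miR-212-5p, an activity-induced neuronal miRNA (0.85 ± 0.15, adjusted p = 0.00906), all 3 in 5 of 5 libraries kept. miR-128-1-5p (log2 fold change -1.31 ± 0.27, edgeR adjusted p = 0.0134), miR-34a-5p (-1.22 ± 0.31, adjusted p = 0.0326) and miR-181a-5p (mir-181a-2) (-1.15 ± 0.27, adjusted p = 0.0216) fell in 5 of 5. Without the library that carried miR-215-5p, miR-34a-5p had an edgeR adjusted p of 0.0660. In all 26 passed, 17 higher and 9 lower, and 13 higher and 9 lower without that library (15 in both). The brain Ldlr-KO count ran from 4 (without Ldlr-KO WD replicate 7) to 45 (without Ldlr-KO chow unnumbered replicate). Of the largest brain calls, miR-128-1-5p ended in 1 refit, miR-34a-5p in 8 and miR-181a-5p (mir-181a-2) in 3 (highest edgeR adjusted p 0.0514 without Ldlr-KO WD replicate 7, 0.0875 and 0.0733 without C57Bl/6 WD replicate 8).

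In brain of Pcsk9-KO mice miR-30b-5p fell from 2551 ± 1019.8 to 1172 ± 101 CPM (n = 6 each; log2 fold change -1.08 ± 0.21, edgeR adjusted p = 0.0133), with miR-497-5p (-1.20 ± 0.24, adjusted p = 0.0133) and miR-29a-5p (-1.04 ± 0.30, adjusted p = 0.0459). miR-370-3p (log2 fold change 1.15 ± 0.33, edgeR adjusted p = 0.0459) and miR-409-3p (0.86 ± 0.19, adjusted p = 0.0154) of the Dlk1-Dio3 locus and miR-1843b-3p (0.83 ± 0.24, adjusted p = 0.0459) rose. In all 35 passed, 19 higher and 16 lower, and 24 higher and 19 lower without the library that carried miR-215-5p (35 in both). The brain Pcsk9-KO count ran from 10 (without Pcsk9-KO chow replicate 1) to 82 (without C57Bl/6 chow replicate 3). It was 59 with DESeq2. Of the largest brain calls, miR-370-3p ended in 10 refits, miR-1843b-3p in 13 and miR-29a-5p in 13 (highest edgeR adjusted p 0.0996 without Pcsk9-KO chow replicate 2, 0.108 without Pcsk9-KO chow replicate 1, 0.109 without Pcsk9-KO WD replicate 6). In the brain interaction test 0 (edgeR; 58 at unadjusted p below 0.05; 1 with DESeq2) miRNAs passed, and 1 without that library. Within brain genotypes the diet test called 8 in C57Bl/6, 0 in Ldlr-KO (95 at unadjusted p below 0.05; 29 with DESeq2) and 0 in Pcsk9-KO (27 at unadjusted p below 0.05; 2 with DESeq2), and 4, 12 and 0 without it.

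**Figure D4:**
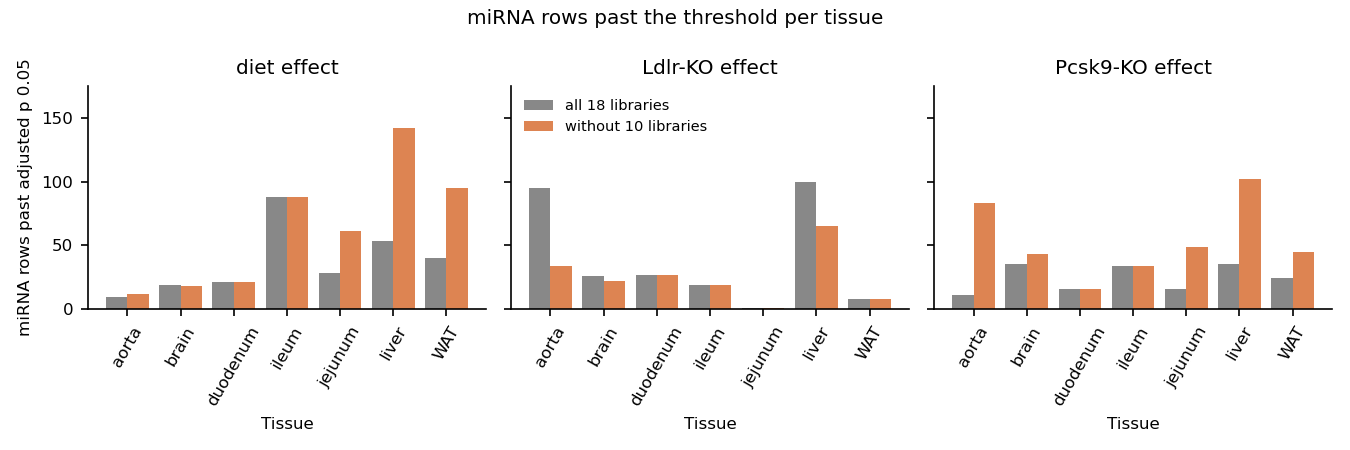
Number of miRNAs past an adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg) per tissue for the diet, Ldlr-KO and Pcsk9-KO contrasts, with all 18 libraries (grey) and without the 10 that stood apart (orange). In liver the diet count was 53 with all libraries and 56 higher and 86 lower without the 2 that stood apart.

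Calls were summed over the 7 tissues and the diet, Ldlr-KO and Pcsk9-KO contrasts, in parentheses without the 10 libraries. The let-7 family had 29 higher and 20 lower (45 and 26). The macrophage and inflammation list had 10 and 18 (18 and 20), and the leukocyte list 10 and 14 (15 and 18). The Dlk1-Dio3 locus had 18 higher and 12 lower (20 and 20), the lipid metabolism list 20 higher and 24 lower (29 and 45), the intestinal epithelium list 19 higher and 1 lower (23 and 13), and the neuron and glia list 7 higher and 11 lower (9 and 16). miR-17-92 and its paralogs had 8 higher and 10 lower (11 and 25), and the miR-183 cluster 2 and 2 (1 and 8). The miR-34 family had 5 and 6 (7 and 2), and adipocyte and thermogenic miRNAs 3 and 9 (3 and 18). Erythroid miRNAs had 1 and 3 (1 and 3). Smooth muscle miRNAs had 6 higher and 3 lower (7 and 11), and striated muscle 0 and 1 (0 and 2). Mesenchymal miRNAs had 7 and 4 (12 and 8), and endocrine 1 and 2 (1 and 2). Of the 2 endothelial miRNAs, miR-126a-5p rose with diet in duodenum (log2 fold change 0.47 ± 0.13, edgeR adjusted p = 0.0337; -0.02 with total counts) and jejunum (0.42 ± 0.11, adjusted p = 0.0337) and in ileum of Pcsk9-KO mice, as given above. Without the 10 libraries it also rose in jejunum and aorta of Pcsk9-KO mice, and miR-126a-3p fell in the latter. Over 306 combinations of list, tissue and contrast, camera called 26 at the preset correlation of 0.01 and 0 with an estimated correlation. The 26 included intestinal epithelium (duodenum diet, jejunum diet, liver Ldlr-KO) and macrophage and inflammation (duodenum diet, jejunum diet, ileum diet, aorta diet). let-7 passed in duodenum Ldlr-KO, duodenum Pcsk9-KO, jejunum Ldlr-KO, liver diet, liver Pcsk9-KO, aorta Pcsk9-KO and brain diet. Dlk1-Dio3 passed in duodenum Pcsk9-KO, jejunum Ldlr-KO, ileum Ldlr-KO, liver diet and WAT diet, and neuron and glia in jejunum Ldlr-KO. Others were miR-17-92 (ileum Pcsk9-KO), erythroid (liver Ldlr-KO), adipocyte and thermogenic (WAT diet), leukocyte (WAT diet) and miR-34 family (WAT Ldlr-KO, aorta diet). The fry test, which asks whether a list moves one way on balance, called 21.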

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

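Chosen after the results were seen were the tests of wrong tubes and of loss of Ldlr in liver, of mixed reads in brain and WAT, and of blood and loss of Ldlr in aorta; the others were written before their results were seen.

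By the interaction test 10 named miRNAs passed, but with all libraries chance could not be excluded for the number of calls (aorta 7 of 100 splits, ileum 9 of 100). In aorta these were miR-34c-5p, let-7d-3p, miR-328-3p, miR-92b-3p, miR-214-3p, miR-574-3p and miR-615-3p, each at an edgeR adjusted p of 0.0187, miR-146b-5p at 0.0320 and miR-423-5p at 0.0324, and in ileum miR-92a-3p (mir-92a-2) at 0.0263. With each of 18 libraries left out in turn, calls ended in 6 refits for miR-34c-5p, let-7d-3p, miR-328-3p, miR-92b-3p, miR-214-3p and miR-615-3p, in 8 for miR-574-3p, 15 for miR-146b-5p, 17 for miR-423-5p and 13 for miR-92a-3p (mir-92a-2). The highest edgeR adjusted p were 0.104 (aorta, without Ldlr-KO WD unnumbered replicate; 0.105 for miR-146b-5p), 0.131 for miR-423-5p without Ldlr-KO WD replicate 7m, and 0.173 in ileum without C57Bl/6 WD replicate 7. The diet log2 fold change of let-7d-3p in aorta was 0.19 ± 0.73 in C57Bl/6, -5.60 ± 0.88 in Ldlr-KO and -0.42 ± 0.73 in Pcsk9-KO. Without the libraries labelled Ldlr-KO aorta chow replicates 4f and 4m, the interaction edgeR adjusted p values of the 9 aorta miRNAs were, in the order above, 0.0391, 0.199, 0.583, 0.996, 0.970, 0.922, 0.556, 0.333 and 0.803.

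Intestinal miRNAs in libraries labelled liver, brain or WAT were weighed first. In the 2 labelled Ldlr-KO liver, miR-122-5p was at most 0.00586% of the median of the other liver libraries. Small intestine in place of liver would give this, which argues for a wrong label or tube. The median miR-215-5p share over 6 Ldlr-KO liver libraries was 0.533%. With 2 of 6 high, it had to be low, so loss of Ldlr stays open. In the library labelled Ldlr-KO brain WD replicate 5 the neuron and glia miRNAs stood at a median ratio of 0.797 to the other brain libraries, against a wrong tube; mixed reads stay open, since the intestinal list, at 9.66, was read in a library picked out for an intestinal miRNA. The libraries labelled C57Bl/6 WAT chow replicates 1 and 2 held the intestinal list at 15.98 and 8.79 times the other WAT libraries. WAT-enriched miRNAs stood at 0.496 and 0.935, against a wrong tube for replicate 2. Replicate 1 had conflicting labels and was nearest ileum (correlation 0.936, WAT 0.926), so this stays open. Mixed reads stay open, as above. The library labelled Ldlr-KO WAT WD replicate 5 held both sets at 24.1 and 0.0585, the latter inside the range of ileum libraries (0.0339 to 0.194). Small intestine in place of WAT or a mixture may explain it. No biological explanation was tested for the brain and WAT libraries.

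The libraries labelled Ldlr-KO aorta chow replicates 4f and 4m were weighed next, and low depth is argued against, since other aorta libraries thinned to the lowest total kept a correlation of at least 0.979. Blood stays open, as the GC bias below may have moved miR-144-3p (log2 ratio -6.05) and miR-486-5p (5.26). Loss of Ldlr on chow stays open, since it could be read in 1 other library of the group alone (correlation 0.985). A bias by GC content may contribute: the log2 ratio to the other aorta libraries followed hairpin GC share (Spearman rho 0.434 over 270 miRNAs; 0.429 in 4f and 0.435 in 4m, and -0.158 to 0.150 in the other aorta libraries). Which step gave rise to it was not tested.

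miRNAs that differ between a knockout and C57Bl/6 were weighed for an effect of donor DNA around the targeted gene. Of miRNAs within 20 Mb of Ldlr or Pcsk9, 7 of 17 were called in at least 1 tissue (odds ratio 1.502, Fisher p = 0.436, and 2.17 without the 10 libraries). The odds ratio above 3 set beforehand was not seen, but 17 miRNAs are few, so donor DNA stays open. Loss of the targeted genes remains open and untested.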

How the results depend on the processing

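Leaving out the 10 libraries, using 1 entry per mature miRNA and leaving out aorta without a block were chosen after the results were seen; the other alternatives were planned. The alternatives were followed for the largest changes of each tissue and contrast and for the lists past the threshold, and of these 0 reversed in the alternatives chosen beforehand or with 1 entry per mature miRNA. Of the list members, 3 other calls changed sign with total-count scaling, miR-126a-5p in ileum of Pcsk9-KO mice (log2 fold change 0.42 to -0.04) and with diet in duodenum (log2 fold change 0.47 to -0.02), and miR-194-5p (mir-194-2) with diet in duodenum (log2 fold change 0.47 to -0.05). Other list members named in the text were not followed when libraries were left out in turn. With RLE scaling 140 of these calls stayed past the threshold and 5 did not. Of the miRNA calls among them with a value, 116 of 116 did with DESeq2, 81 of 119 with total-count scaling, 103 of 119 without a filter, 102 of 107 with 1 entry per mature miRNA, 27 of 41 with an additive model and 22 of 74 with a block. DESeq2 gave no adjusted p to miR-194-1-3p, miR-215-3p and miR-215-5p in liver of Ldlr-KO mice, where its outlier rule (Cook's distance) set the p value aside, so these 3 calls are not counted as kept or lost. Over all refits that left out 1 library, 1546 kept the direction and the call and 596 kept only the direction. Without the 10 libraries 86 kept the call, 19 kept only the direction and 4 reversed: miR-194-1-3p and miR-215-3p in liver of Ldlr-KO mice, to log2 fold changes of -1.15 and -0.72, and the camera tests of the Dlk1-Dio3 and the neuron and glia lists in jejunum of Ldlr-KO mice, to adjusted p values of 0.129 and 0.970.

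With DESeq2 the counts that moved were diet aorta 71, brain 49, liver 84; Pcsk9-KO aorta 27, brain 59, jejunum 30, WAT 42; interaction aorta 102, brain 1, ileum 8, jejunum 2, liver 2, WAT 29; diet in C57Bl/6 aorta 1, brain 20, duodenum 12, jejunum 5, liver 61, WAT 52; diet in Ldlr-KO brain 29, duodenum 12, ileum 21, jejunum 16, liver 2, WAT 20; diet in Pcsk9-KO brain 2, ileum 6, jejunum 2, liver 10, WAT 6; Ldlr-KO ileum 45, jejunum 54, WAT 21. Under RLE scaling they became diet brain 9; diet in Pcsk9-KO WAT 0; lists brain 2. Using total-count scaling gave Pcsk9-KO aorta 33, duodenum 51, ileum 88, jejunum 57; diet brain 50, duodenum 119, jejunum 62, WAT 19; diet in C57Bl/6 brain 3, duodenum 2, ileum 7, liver 15, WAT 8; diet in Ldlr-KO brain 28, duodenum 41, ileum 23, jejunum 46, WAT 0; Ldlr-KO ileum 12, jejunum 0, liver 55, WAT 5; diet in Pcsk9-KO jejunum 0, WAT 0; enriched aorta 22, brain 201, WAT 19. Without a low-count filter the moved counts were diet aorta 0, brain 11, jejunum 18; Pcsk9-KO aorta 7, duodenum 9, liver 20; diet in C57Bl/6 duodenum 0; Ldlr-KO WAT 5; diet in Pcsk9-KO WAT 0. With a block by mouse number the counts that moved were Ldlr-KO aorta 1, brain 2, ileum 0, jejunum 2, liver 3, WAT 0; Pcsk9-KO aorta 1, brain 20, duodenum 3, ileum 17, liver 3, WAT 0; enriched WAT 27 (run without aorta). Leaving out aorta without a block gave 27 too, so this move was that of the tissues compared. Under an additive model they became diet aorta 0, brain 0. Using the genotype's 6 libraries alone gave diet in Ldlr-KO aorta 0, ileum 2, jejunum 0, WAT 0; diet in C57Bl/6 brain 0, duodenum 0, jejunum 2, liver 81; diet in Pcsk9-KO ileum 16, jejunum 8, liver 17, WAT 6. With an estimated correlation 0 lists passed in any of the 7 tissues (aorta 0, brain 0, duodenum 0, ileum 0, jejunum 0, liver 0 and WAT 0), by camera. With a log2 fold change of at least 2 the counts that moved were enriched aorta 13, ileum 0, liver 6, WAT 1. Under 1 entry per mature miRNA they became diet aorta 35, brain 9; Ldlr-KO WAT 4. Leaving out the 10 libraries gave Ldlr-KO aorta 34, liver 65; Pcsk9-KO aorta 83, jejunum 49, liver 102, WAT 45; interaction aorta 11, brain 1, jejunum 2, liver 4, WAT 9; diet in C57Bl/6 aorta 2, brain 4, jejunum 12, liver 120, WAT 37; diet in Ldlr-KO aorta 11, brain 12, jejunum 20, liver 62, WAT 57; diet jejunum 61, liver 1.4e+02 (rounded, 56 higher and 86 lower), WAT 95; diet in Pcsk9-KO liver 21, WAT 23; lists aorta 10, brain 3, ileum 5, liver 11. The cause of the other moves was not tested.

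When each library was left out in turn, the counts ran as follows: interaction aorta 0 to 293, brain 0 to 6, duodenum 0 to 1, ileum 0 to 5, jejunum 0 to 1, liver 0 to 2, WAT 0 to 18; diet aorta 0 to 272, brain 0 to 97, duodenum 10 to 29, jejunum 11 to 53, liver 30 to 100, WAT 23 to 1.3e+02 (rounded, 48 higher and 78 lower); diet in C57Bl/6 aorta 0 to 2, brain 0 to 26, duodenum 0 to 4, ileum 14 to 69, jejunum 1 to 3, liver 7 to 68, WAT 0 to 108; diet in Ldlr-KO aorta 93 to 318, brain 0 to 81, duodenum 0 to 7, ileum 2 to 33, jejunum 1 to 31, liver 0 to 25, WAT 1 to 18; Ldlr-KO aorta 35 to 285, brain 4 to 45, duodenum 7 to 55, ileum 6 to 28, jejunum 1 to 74, liver 22 to 123, WAT 4 to 31; Pcsk9-KO aorta 5 to 88, brain 10 to 82, duodenum 1 to 26, ileum 15 to 43, jejunum 5 to 19, liver 9 to 52, WAT 0 to 78; diet in Pcsk9-KO ileum 0 to 6, jejunum 0 to 2, liver 0 to 7, WAT 0 to 11. For the other numbers of calls, the enriched miRNAs among them, each refit stayed within 1.5 times. In the fit without the 10 libraries, 2 groups held 1 library, which was assumed to vary like the other groups.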

Other observations

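The tests of other splits were written before their results were seen, those without the libraries that stood apart only after the results of the others. Libraries of each tissue were split at random into groups of the same sizes, the real split counted among 100, and the number of splits with as many calls is given with the real count and the highest of the others. In duodenum, chance could be excluded for diet (1 of 100, 21 against 1), Ldlr-KO (1 of 100, 27 against 11) and Pcsk9-KO (1 of 100, 16 against 1). The interaction gave 100 of 100 (0 against 6). In jejunum, chance could be excluded for diet (1 of 100; 28 against 11), Pcsk9-KO (1 of 100; 16 against 1) and not for Ldlr-KO (3 of 100; 1 against 2), interaction (100 of 100; 0 against 26). In ileum, chance could be excluded for diet (1 of 100, 88 against 37) and Pcsk9-KO (1 of 100, 34 against 17). Ldlr-KO gave 2 of 100 (19 against 33) and the interaction 9 of 100 (3 against 21). In liver, chance could be excluded for diet (1 of 100, 53 against 45), Ldlr-KO (1 of 100, 100 against 43) and Pcsk9-KO (1 of 100, 35 against 1). The interaction gave 100 of 100 (0 against 84). In WAT, chance could be excluded for diet (1 of 100; 40 against 20), Pcsk9-KO (1 of 100; 24 against 4) and not for Ldlr-KO (7 of 100; 8 against 37), interaction (100 of 100; 0 against 20). In aorta, chance could be excluded for Ldlr-KO (1 of 100, 95 against 80) and Pcsk9-KO (1 of 100, 11 against 1). Diet gave 2 of 100 (9 against 30) and the interaction 7 of 100 (66 against 73). In brain, chance could be excluded for diet (1 of 100, 19 against 2) and Pcsk9-KO (1 of 100, 35 against 7). Ldlr-KO gave 2 of 100 (26 against 33) and the interaction 100 of 100 (0 against 1). Some splits called several times the real number (interaction in ileum, diet in aorta, Ldlr-KO in WAT, diet within Ldlr-KO in jejunum, ileum and WAT). The reason was not tested.

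In jejunum, liver, WAT, aorta and brain the real split holds libraries that stood apart. Its count there does not bear on knockout or diet alone. The remaining libraries were split too, in all ways where these were fewer than 100. For jejunum, chance could be excluded for diet (1 of 100; 61 against 12) and Pcsk9-KO (1 of 100; 49 against 10) and not for Ldlr-KO (7 of 100; 1 against 3) and interaction (5 of 100; 2 against 35). For liver, chance could be excluded for diet (1 of 100, 56 higher and 86 lower against 29), Ldlr-KO (1 of 100, 65 against 21) and Pcsk9-KO (1 of 100, 102 against 36). The interaction gave 5 of 100 (4 against 116). For WAT and aorta a group kept 1 library, so no verdict on chance is drawn there. The splits with as many calls in WAT were 1 of 100 for diet, 1 of 80 for Pcsk9-KO, 3 of 100 for interaction and 2 of 40 for Ldlr-KO. Those in aorta were 1 of 100 for diet, 1 of 80 for Ldlr-KO, 1 of 100 for Pcsk9-KO and 2 of 100 for interaction. For brain, chance could be excluded for Ldlr-KO (1 of 100, 22 against 6) and Pcsk9-KO (1 of 100, 43 against 6). Diet gave 3 of 100 (18 against 110) and the interaction 19 of 100 (1 against 45). Again some splits called several times the real number (diet and interaction in brain, and interaction in jejunum, liver and WAT), for untested reasons.

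Within a genotype, 3 against 3 libraries make 10 splits, too few for a share under 0.05; in the order C57Bl/6, Ldlr-KO and Pcsk9-KO the splits with as many calls were duodenum 1 (1 against 0), 10 (0 against 6), 10 (0 against 0); jejunum 1 (1 against 0), 5 (3 against 98), 2 (1 against 1); ileum 1 (60 against 0), 5 (9 against 36), 10 (0 against 0); liver 1 (33 against 0), 10 (0 against 95), 10 (0 against 0); WAT 1 (21 against 0), 3 (9 against 28), 1 (1 against 0); aorta 10 (0 against 0), 1 (135 against 118), 10 (0 against 0); brain 1 (8 against 0), 10 (0 against 11), 10 (0 against 0). For enriched miRNAs, shuffles of the tissue labels with as many were duodenum 1 of 40 (3 against 0) and ileum 2 of 40 (7 against 8). They were 1 of 40 in liver (15 against 0), WAT (8 against 0), aorta (40 against 0) and brain (130 against 0). Chance could be excluded in these except ileum. In jejunum the real count was 0 (40 of 40, 0 against 0), so there was nothing to test. For the list tests 58 of 100 splits gave as many calls (26 against 47), so chance could not be excluded for their number.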
